A study of Homo sapiens with 212 samples.

How the data were processed

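The deposited values are read counts per Entrez gene for 212 samples, 1 column per sample, with 22568 gene identifiers. Per the submitters' processing notes, reads were aligned to hg19 (GRCh37) with Bowtie 0.12.8. Per the labels, libraries were TruSeq libraries from RNA with an integrity number above 7 and tissue of high tumour cell content, sequenced at 100 bp as single-end or paired-end reads on a HiSeq2500, and the authors counted reads with GenomicFeatures. The sources used here do not state which samples were single-end or paired-end, nor the strand, multiple mapping and exon rules of the counting. No reads were realigned here. Values were checked to be non-negative whole numbers, and no sample's file was identical to another's. The 5 closest pairs of samples differed by more than sampling error, with a smallest chi-square per degree of freedom of 22.41, and the highest correlation of log2 CPM was 0.992.

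Identifiers were turned into symbols with the gene table provided, which follows GRCh38 and not hg19, so no coordinates were used. Symbols were found for 22437 identifiers, and the 131 without one held a median of 0.404% of a sample's counts (at most 1.05%). Genes of the Y chromosome, XIST and TSIX (70 in all) were left out, leaving 22367. DAXX, AIF1 and PRSS2 are absent and were not analysed here, and neither were SSTR4 and 1 posterior HOX gene, which fell to the expression filter. Total counts ran from 1.27 to 351M with a median of 30.0M. The next lowest library held 13.9M. Libraries over 90M numbered 19, of which 17 were rectal and 2 were small intestinal liver metastases, and medians were 164M in rectal and 29.2M in other libraries. Rectal origin and depth are therefore nearly the same division of the samples.

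Groups came from the organ of origin and the sampled site in the labels. The 1 mesenteric metastasis was not compared, and the other samples form 8 groups. Every contrast, gene list, alternative and rule for naming genes was fixed before the data were examined, except where a test is said to have been added later. Sample replicate numbers are names only.

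Gene tests used edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the 8 groups, which left 20936. Library sizes were scaled by TMM, dispersions were estimated (common dispersion 0.797), and 10 contrasts were tested in 1 quasi-likelihood model over the 8 groups, including the difference between the liver metastasis effects of the small intestine and the pancreas. P-values were two-sided and adjusted by Benjamini-Hochberg within each contrast, with 0.05 as the threshold. Standard errors are the absolute log2 fold change divided by the square root of the F statistic. Folds of edgeR compare arithmetic means on the count scale, so a few high samples can set them, and medians are given for this reason. The sample of the patient who contributed 2 was kept, and a fit with 1 sample per patient was run beside it.

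Genes named in each contrast had an adjusted p under 0.05, a median of at least 5 CPM in the higher group, and medians in the direction of the fold. Of these the 8 with the largest and the 8 with the smallest log2 fold change were eligible, or 4 and 4 where a group had fewer than 10 samples and for the difference of contrasts. Up to 4 members of a described list that passed and up to 2 that did not were named with it. CHGA, SYP, TPH1, INS, GCG, PDX1, CDX2, SSTR2, MKI67, MEN1, ATRX, ALB and PRSS1 could be named in any contrast. Some genes that this rule allows are not reported here. Genes that overlap, lie antisense or share sequence, such as INS-IGF2 with INS and IGF2, HP with HPR and TXNL4B, GHRL with GHRLOS, and the MBD3L and HNRNPCL copies, have uncertain separate values. Folds against a group with no count, as for INS in rectal primaries and node metastases and GAST in rectal primaries, are not given.

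Of 30 gene lists, 29 were tested. The list of MHC class I antigen presentation was not, because 4 of its 14 members were measured and at least 80% was required. A list score is the mean over members of log2(TMM CPM + 0.5). Scores were compared by two-sided permutation of sample labels with 100000 draws, whose smallest p is 1e-05, and by every arrangement for rectal primaries and node metastases, whose smallest p are 0.0027 and 0.00073 (0.013 with 1 primary left out). These 261 tests were adjusted together by Benjamini-Hochberg, and 59 passed. The difference between liver metastasis effects was tested for each score by 20000 permutations of residuals (smallest p 5e-05), adjusted over the lists, and 6 passed. For each list the members higher, lower and not passing are counted at the adjustment over all genes, and again adjusted over the list alone. Direction shares count the samples of a contrast's first group above or below the median of the other.

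Alternatives, fixed beforehand, were DESeq2 size factors, no expression filter, DESeq2 1.42.0, limma-voom 3.58.1, the Wilcoxon rank-sum test (exact where a group had fewer than 10 samples), fits of the groups of a contrast alone, log2 library size as a covariate, leaving out the lowest 10% of libraries by depth, host tissue scores as covariates, 1 sample per patient, and leaving out each rectal primary or node sample in turn. Host tissue scores were those of the hepatocyte, acinar, enterocyte, smooth muscle, T cell and B cell lists. Members of these lists are adjusted for a score that contains them, so their values in that fit do not test their own differences. Added later were total counts over 90M as a covariate, deep libraries alone, deep small intestinal libraries left out, the library under 10M left out, host list genes not counted, and libraries with a neuroendocrine score under 5 left out.

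The gene tests were tested on simulated data made with known changes, on 20792 genes. For pancreatic liver metastases against primaries edgeR recovered 63.0% of 2-fold and 90.9% of 4-fold changes with 36 false calls, limma-voom 54.0% and 84.8% with 7, and the Wilcoxon test 57.0% and 85.9% with 3. For small intestinal node metastases against primaries edgeR recovered 34.0% and 61.0% with 6 false calls. For rectal liver metastases against primaries edgeR recovered 6.1% and 32.0% with 8 false calls, limma-voom 15.2% and 47.0% with 191, and the Wilcoxon test 0% of both. The simulated counts came from a negative binomial model without samples that stand apart, so real data can give more false calls. With permuted labels, edgeR fits of the real pancreatic primaries and liver metastases called a median of 308 genes (highest 1698). Scores, permutations and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.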

Results

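RNA-seq read counts per gene were collected from 212 gastro-entero-pancreatic neuroendocrine tumours, which are tumours of hormone-secreting cells of the gut and pancreas. The samples are separate patients' tumours, apart from 1 patient who contributed 2. Pancreatic tumours gave 83 primary and 30 liver metastasis samples. Small intestinal tumours gave 44 primary, 8 lymph node metastasis and 28 liver metastasis samples and 1 mesenteric metastasis, which entered no comparison. Rectal tumours gave 3 primary, 4 lymph node metastasis and 11 liver metastasis samples. Total counts had a median of 28.8M (M for mega) in pancreatic primaries (range 15.4 to 43.1), 30.4M in pancreatic liver metastases (19.8 to 50.7) and 28.7M in small intestinal primaries (15.6 to 43.8). They were 27.3M in small intestinal node metastases (13.9 to 32.3) and 30.7M in small intestinal liver metastases (1.27 to 180). Rectal libraries were deeper, with medians of 184M in primaries (158 to 203), 156M in node metastases (52.1 to 178) and 171M in liver metastases (94.2 to 351). A median of 20102 genes had a count (range 16963 to 21439). Gene differences are log2 fold changes ± SE from edgeR, levels are group medians in counts perM (CPM), and genes described as higher, lower, risen or fallen passed edgeR's test. A list score is the mean log2 level of a fixed gene list in a sample, and its differences are given ± SE.

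The first comparison asked how primary tumours differ with the organ of origin, setting the small intestine (n = 44) against the pancreas (n = 83). Small intestinal primaries carried far more RNA of some genes of the enterochromaffin cell, the serotonin cell of the gut. TAC1, which encodes the precursor of substance P, was higher by 5.12 ± 0.64 (624 against 0.601 CPM), and TPH1, the first enzyme of serotonin synthesis in the gut, by 3.10 ± 0.56 (1003 against 3.09 CPM). The homeobox gene CDX2, active in the developing gut, was higher by 3.56 ± 0.44 (81.8 against 0.949 CPM). Pancreatic primaries carried more of the islet hormone genes INS (insulin) and GCG (glucagon), with small intestinal minus pancreatic differences of -8.65 ± 1.38 and -8.03 ± 1.07. Medians were 0 against 5.50 CPM for INS and 0.292 against 14.0 CPM for GCG. Pancreatic means were 5004 CPM (SD 20020) and 2336 CPM (SD 8030), so a few high samples set the size of these folds. Of 20936 genes tested, 9620 passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 4417 higher and 5203 lower in small intestinal primaries, and 3788 of them differed at least 2-fold.

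Among the serotonin and enterochromaffin genes, 6 of 14 were higher in small intestinal primaries, 5 lower and 3 did not pass (6 and 5 adjusted over the list alone). The vesicular monoamine transporter SLC18A1 (4.29 ± 0.57) and the transcription factor LMX1A (4.22 ± 0.50) were among the higher ones, while MAOB (-0.41 ± 0.37) did not pass. The score was higher by 1.92 ± 0.21, in 39 of 44 samples (adjusted two-sided permutation p = 1.24e-04, from the smallest p that 100000 draws can give, 1e-05). Of the 6 islet hormone genes, 5 were lower and 1 higher (5 and 1 adjusted over the list alone), and the score differed by -2.75 ± 0.28, with 43 of 44 samples below the pancreatic median. Islet transcription factors followed, with 12 of 18 lower, 1 higher and 5 not passing (12 and 2 adjusted over the list alone). MAFA (-7.95 ± 0.95), a beta cell factor, and IRX1 (-5.85 ± 0.75) and NKX6-1 (-4.71 ± 0.70) were lower, as was PDX1 (-1.86 ± 0.59), while HHEX (0.78 ± 0.35) did not pass. Their score was below the pancreatic median in 44 of 44 samples (-1.77 ± 0.16). Intestinal transcription factors were higher for 7 of 11 members and lower for 1 (7 and 1 adjusted over the list alone), among them ATOH1 (6.21 ± 0.55) and CDX1 (5.45 ± 0.52), with a score difference of 1.11 ± 0.18 in 38 of 44 samples.

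Anterior HOX genes were higher in small intestinal primaries for 10 of 15 members and lower for none (10 and 0 adjusted over the list alone), led by HOXC4 (2.92 ± 0.44) and HOXC5 (2.84 ± 0.47). Their score was higher in 43 of 44 samples (0.97 ± 0.14). Posterior HOX genes were mixed, 5 of 15 higher and 4 lower (6 and 5 adjusted over the list alone), with HOXB9 at 3.32 ± 0.57 and HOXC13 at -3.74 ± 0.73 (score 0.40 ± 0.12, 35 of 44 samples, adjusted permutation p = 0.00962). Of 22 neuroendocrine secretory genes, 1 was higher, 8 were lower and 13 did not pass (1 and 8 adjusted over the list alone). CHGA, the granule protein chromogranin A used as a serum marker, was the higher one (2.10 ± 0.42, 27440 against 2073 CPM), while VGF (-3.91 ± 0.53) and the synaptic vesicle gene SYP (-0.97 ± 0.22) were lower. The score itself did not pass (-0.43 ± 0.25, adjusted permutation p = 0.207, 39 of 44 samples below the pancreatic median). Somatostatin receptor genes were lower for 3 of the 4 tested (3 adjusted over the list alone), with SSTR3 at -3.28 ± 0.58 and SSTR2 at -1.20 ± 0.32, while SSTR5 (0.02 ± 0.39) did not pass. That score fell in 38 of 44 samples (-0.71 ± 0.21, adjusted permutation p = 0.00873).

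Hypoxia and glycolysis genes were lower in small intestinal primaries for 11 of 16 members (12 adjusted over the list alone), including CA9 (-2.68 ± 0.68) and VEGFA (-1.45 ± 0.22). That score was lower in 28 of 44 samples (-0.41 ± 0.13, adjusted permutation p = 0.0477). Genes recurrently mutated in these tumours were higher for 5 of 11 members and lower for none (5 and 0 adjusted over the list alone), all by less than 2-fold, such as CDKN1B (0.48 ± 0.10) and MEN1 (0.31 ± 0.10), with ATRX (0.23 ± 0.12) not passing (score 0.23 ± 0.04, 40 of 44 samples). Histone deacetylase genes were higher for 4 of 11 (4 adjusted over the list alone), with HDAC4 at 0.61 ± 0.12 (score 0.25 ± 0.05, 38 of 44 samples). Gut peptide hormone genes were split, 2 of 12 higher and 5 lower (2 and 7 adjusted over the list alone), with secretin SCT at 2.68 ± 0.42 and VIP at -4.34 ± 0.87, and their score did not pass (-0.13 ± 0.13, adjusted permutation p = 0.564). Proliferation genes had 4 of 27 lower (2 adjusted over the list alone), MKI67 stood at 0.16 ± 0.34 and did not pass, and neither did the score (-0.35 ± 0.21, adjusted permutation p = 0.237). Interferon-stimulated genes were higher for 6 of 17 and lower for 1 (6 and 1 adjusted over the list alone), with MX2 at 1.07 ± 0.22 and IFI6 at -1.21 ± 0.27, and a score difference that did not pass (0.34 ± 0.13, adjusted permutation p = 0.0866).

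Markers of other cell types moved with these genes. Smooth muscle genes were higher in small intestinal primaries for 10 of 10 members (10 adjusted over the list alone), led by DES (6.51 ± 0.58, 115 against 1.08 CPM) and ACTG2 (5.69 ± 0.48). That score was higher in 35 of 44 samples (1.97 ± 0.35). Goblet and Paneth genes were higher for 7 of 8 (7 adjusted over the list alone; DEFA5 10.88 ± 0.78, MUC2 9.22 ± 0.67) and enterocyte genes for 8 of 10 (8 adjusted over the list alone; FABP2 8.20 ± 0.58), with scores higher in 26 and 28 of 44 samples (1.56 ± 0.42 and 1.04 ± 0.34). Colonocyte genes were higher for 4 of 8 and lower for 2 (4 and 2 adjusted over the list alone), with SLC26A3 at 4.72 ± 0.38 and a score difference of 0.41 ± 0.16 in 33 of 44 samples. Pancreatic acinar genes were lower for 17 of 18 (17 adjusted over the list alone), with CTRB2 at -10.09 ± 1.34 and PRSS1, trypsinogen, at -5.99 ± 1.10. The score was lower in 31 of 44 samples (-1.14 ± 0.28). T cell genes were higher for 9 of 12 (9 adjusted over the list alone; CD3G 1.40 ± 0.33; score 0.67 ± 0.18, 36 of 44 samples) and endothelial genes lower for 10 of 12 (11 adjusted over the list alone; KDR -1.16 ± 0.20; score -0.68 ± 0.15, 33 of 44 samples). Hepatocyte genes had 3 of 22 higher and 12 lower (3 and 12 adjusted over the list alone), with FGB at -5.16 ± 0.86 and ALB at -0.31 ± 0.63, which did not pass, and a score difference of -0.14 ± 0.16. Also higher were the lncRNA ATXN8OS (5.38 ± 0.58), the citrate transporter SLC13A2 (5.01 ± 0.52) and ADAMDEC1 (5.60 ± 0.44), while AGT, angiotensinogen (-6.64 ± 0.69, 12.8 against 296 CPM), and the islet zinc transporter SLC30A8 (-5.30 ± 0.73) were lower.

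Lists that did not pass by score in this comparison were fibroblast and matrix (1 of 19 higher, 10 lower, 2 and 10 adjusted over the list alone; POSTN -3.24 ± 0.44; score -0.40 ± 0.19), duct and bile duct (3 of 8 lower, 3 adjusted over the list alone; MMP7 -3.64 ± 0.75; score -0.51 ± 0.22) and Schwann cell (4 of 6 higher, 1 lower, 5 and 1 adjusted over the list alone; SOX10 2.36 ± 0.35; score 0.30 ± 0.21). B cell and plasma cell genes had 1 of 12 higher and 2 lower (0 and 2 adjusted over the list alone; CR2 -1.87 ± 0.65; score 0.26 ± 0.18), and macrophage genes 1 of 11 lower (1 adjusted over the list alone; LYZ -1.65 ± 0.51; score 0.13 ± 0.16). No member of the Kupffer cell list (4 genes, score 0.10) or the erythroid list (4 genes, score -0.42, median member fold 0.42) passed. With the host tissue scores as covariates PRSS1 stood at 0.07 and no longer passed, but it belongs to the acinar list, whose score is among them. CA9 and CR2 turned to 0.06 and 0.66 with limma-voom and did not pass. HHEX turned to -1.12 with DESeq2 and -0.48 with the Wilcoxon test, and passed as lower in both (adjusted p = 3.1e-04 and 0.0324).

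**Figure D1:**
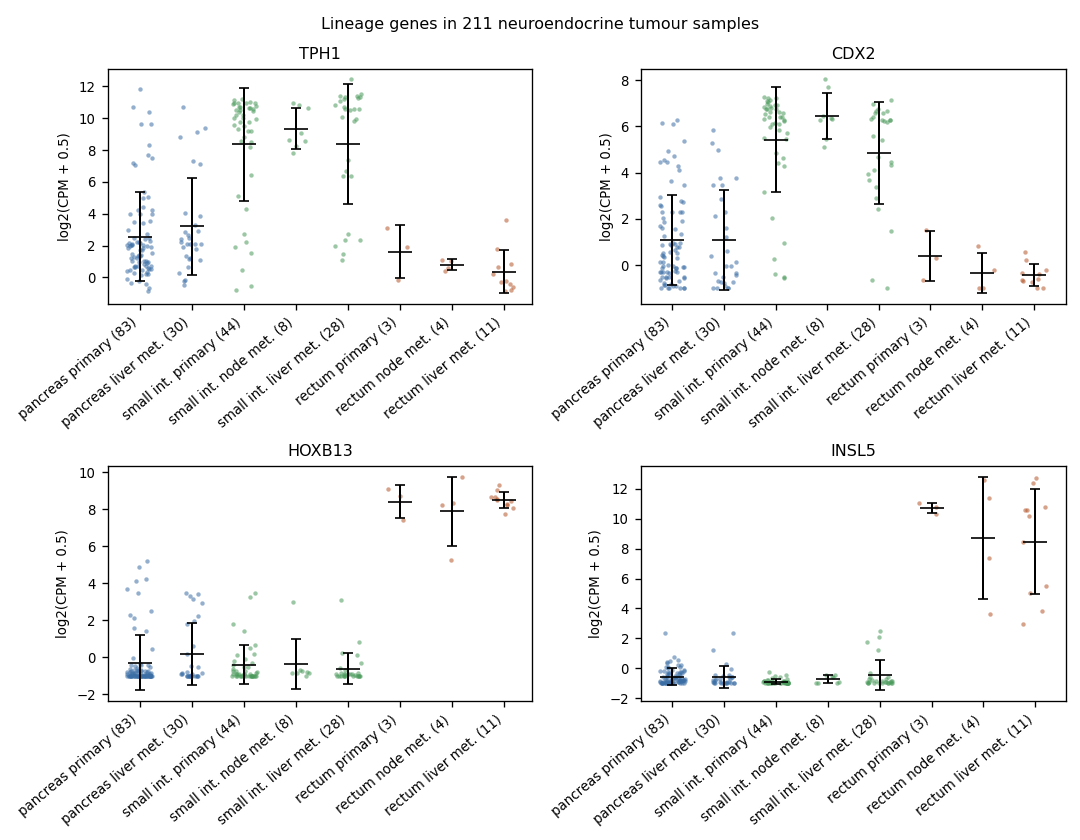
Levels of TPH1, CDX2, HOXB13 and INSL5 in log2(CPM + 0.5) in each sample of the 8 groups, with the group mean and SD as a bar. TPH1 and CDX2 lie high in small intestinal samples, and HOXB13 and INSL5 in rectal samples, where INSL5 has a median of 1160 CPM in liver metastases.

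Liver metastases of pancreatic origin (n = 30) were compared with pancreatic primaries (n = 83) to ask what differs with the site of growth. Genes of liver parenchyma were far higher in the metastases, among them ALB, serum albumin (9.94 ± 0.79, 129 against 2.48 CPM), the plasminogen gene PLG (9.23 ± 0.56), the cytochrome gene CYP2E1 (8.08 ± 0.57) and APOB (7.25 ± 0.74). GCG was lower by -13.05 ± 1.57 (0.0588 against 14.0 CPM), the pancreatic polypeptide gene PPY by -4.39 ± 1.16, the islet glucose-6-phosphatase G6PC2 by -4.22 ± 0.87 and the secreted Wnt modulator SFRP2 by -5.19 ± 0.81 (0.155 against 22.1 CPM). MKI67, the antigen used to grade these tumours, was higher by 1.68 ± 0.36 (16.7 against 7.89 CPM, adjusted p = 1.0e-04 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). In all, 4568 genes passed, 3150 higher and 1418 lower in the metastases, and 2174 differed at least 2-fold. Without the libraries whose neuroendocrine score lay under 5 (4 of 83 primaries and 6 of 30 metastases), 2103 genes passed, 1423 higher and 680 lower, and 1812 were shared with the full set. These metastases were unlike each other. Replicates 1, 25 and 27 had hepatocyte list scores of 12.9, 13.2 and 12.5, so they were rich in liver RNA. Replicates 20, 23 and 28 had 5.13, 0.91 and 0.98.

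All 22 hepatocyte genes were higher in pancreatic liver metastases (22 adjusted over the list alone), SERPINC1 by 10.06 ± 0.62. The score was higher in 22 of 30 samples (3.06 ± 0.71, adjusted two-sided permutation p = 1.24e-04). Without the low neuroendocrine libraries 17 of the 22 were higher and ALB stood at 6.26 ± 0.68. Of the Kupffer cell genes, markers of the liver macrophage, 3 of 4 were higher (3 adjusted over the list alone, and 1 without the low neuroendocrine libraries), with CD5L at 4.71 ± 0.67 and MARCO at 4.34 ± 0.59 (score 0.77 ± 0.31, 20 of 30 samples, adjusted permutation p = 0.0027). HP (8.94 ± 0.90), HPR (9.35 ± 0.84) and TXNL4B (8.20 ± 0.57) were also higher, but they share sequence or a locus and their separate values are uncertain. Islet hormone genes were lower for 4 of 6 members (5 adjusted over the list alone), including SST (-4.31 ± 1.25), while INS (-2.79 ± 1.20) did not pass. This list scored lower in 29 of 30 samples (-2.61 ± 0.28). The overlapping antisense pair GHRL (-5.62 ± 0.89) and GHRLOS (-4.23 ± 0.69) was lower too, its reads not separable without strand. Pancreatic acinar genes went both ways, 7 of 18 higher and 2 lower (9 and 2 adjusted over the list alone), with CELA3B at 2.66 ± 0.75 and CPB1 at -2.34 ± 0.89, and the score did not pass (-0.48 ± 0.58, lower in 22 of 30 samples, median member fold 1.51).

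Proliferation genes were higher in pancreatic liver metastases for 12 of 27 members and lower for none (17 and 0 adjusted over the list alone), with KIF11 at 1.33 ± 0.28 and TOP2A at 1.38 ± 0.41, while CDK1 (0.94 ± 0.38) did not pass. The score missed the threshold (0.66 ± 0.29, higher in 20 of 30 samples, adjusted permutation p = 0.0538), and 16 genes were higher without the low neuroendocrine libraries. Neuroendocrine secretory genes fell for 2 of 22 (1 adjusted over the list alone), SCG5 (-1.03 ± 0.33) and PTPRN2 (-0.65 ± 0.24), with CHGA (-0.21 ± 0.50) and SYP (-0.42 ± 0.25) not passing. Without the low neuroendocrine libraries, which were defined by the score of this list, 0 of 22 passed. That score was lower by -1.15 ± 0.50, in 18 of 30 samples (adjusted permutation p = 0.0163). Islet transcription factors had 2 of 18 lower and 1 higher (2 and 1 adjusted over the list alone), with MAFA at -2.78 ± 0.83 and ONECUT1 at 1.74 ± 0.59. The score was lower in 24 of 30 samples (-0.85 ± 0.27). Intestinal transcription factors were higher for 5 of 11 (6 adjusted over the list alone; CDX1 3.57 ± 0.52, GATA5 2.49 ± 0.58). This list scored higher in 22 of 30 samples (0.47 ± 0.16), while CDX2 (0.07 ± 0.51) did not pass. Without the low neuroendocrine libraries 2 of the intestinal and 0 of the islet factors passed. Posterior HOX genes were higher for 7 of 15 (7 adjusted over the list alone; HOXD11 5.70 ± 0.71, HOXD10 3.95 ± 0.60), but their score was not (0.22 ± 0.21, adjusted permutation p = 0.355).

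Smaller groups also moved in pancreatic liver metastases. Histone deacetylases fell for 2 of 11 (2 lower and 1 higher adjusted over the list alone; HDAC10 -0.56 ± 0.16; 0 without the low neuroendocrine libraries). Their score was lower in 19 of 30 samples (-0.16 ± 0.07). Hypoxia and glycolysis genes rose for 4 of 16 (4 adjusted over the list alone, and 1 of 16 without the low neuroendocrine libraries; ANGPTL4 1.78 ± 0.32, LDHA 0.85 ± 0.26), without a passing score (0.30 ± 0.24). MEN1 was higher by 0.38 ± 0.12, while TPH1 (0.11 ± 0.65), PDX1 (-0.28 ± 0.62), SSTR2 (0.18 ± 0.34) and PRSS1 (1.31 ± 0.86) did not pass. CCN3 (-2.76 ± 0.50) no longer passed without the low neuroendocrine libraries (-0.75 ± 0.32). The count of changed genes was 1804 with limma-voom, 1240 with the Wilcoxon test and 2817 with host tissue scores as covariates, which turned MAFA to 0.01 and ONECUT1 to -1.08. CELA3B turned to -4.19 with DESeq2, where it passed as lower (adjusted p = 4.9e-07), and to -1.56 with limma-voom, where it did not pass.

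In the small intestine, 28 liver metastases were compared with 44 primaries. The largest increases were again in liver genes, with HRG at 10.43 ± 1.07, AHSG at 10.12 ± 1.15, APOA2 at 10.07 ± 1.29 and ALB at 9.89 ± 1.06 (453 against 2.25 CPM). The lower genes included the muscle genes desmin DES (-9.34 ± 1.08, 0.488 against 115 CPM), ACTG2 (-8.47 ± 0.89) and FLNC (-5.68 ± 0.62), the BMP antagonist GREM1 (-5.62 ± 0.78) and the homeobox gene NKX2-3 (-6.85 ± 0.73). Without the low neuroendocrine libraries the muscle genes stood at -8.10 ± 1.02, -7.06 ± 0.83 and -4.36 ± 0.54, GREM1 at -5.49 ± 0.77 and NKX2-3 at -6.46 ± 0.73. Lineage markers of these tumours did not pass, with CHGA at -0.19 ± 0.57, SYP at -0.03 ± 0.27, TPH1 at 0.49 ± 0.73 and CDX2 at -0.45 ± 0.58. In total 3901 genes passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1589 higher and 2312 lower in the metastases, and 2520 differed at least 2-fold.

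Hepatocyte genes were higher for 22 of 22 members (22 adjusted over the list alone). The score was higher in 27 of 28 samples (3.89 ± 0.63). Kupffer cell genes were higher for 3 of 4 (3 adjusted over the list alone; MARCO 5.29 ± 0.78; score 1.18 ± 0.35, 20 of 28 samples) and erythroid genes for 4 of 4 (4 adjusted over the list alone; HBB 3.53 ± 0.59; score 1.10 ± 0.43, 23 of 28 samples, adjusted two-sided permutation p = 0.0283). Smooth muscle genes were lower for 10 of 10 (10 adjusted over the list alone; CNN1 -5.21 ± 0.57, MYH11 -3.44 ± 0.50), and for 9 of 10 without the low neuroendocrine libraries (CNN1 -3.67 ± 0.48). That score was lower in 28 of 28 samples (-2.40 ± 0.37). Fibroblast and matrix genes had 4 of 19 lower and 1 higher (4 and 1 adjusted over the list alone), without a passing score (-0.22 ± 0.24). Goblet and Paneth genes were lower for 8 of 8 (8 adjusted over the list alone; DEFA6 -10.18 ± 1.18; score -1.72 ± 0.42, 24 of 28 samples). Enterocyte genes were lower for 7 of 10 (8 lower and 1 higher adjusted over the list alone; SI -8.93 ± 1.15) and colonocyte genes for 6 of 8, with 1 higher (6 and 1 adjusted over the list alone; GUCA2A -9.06 ± 1.38), but neither score passed (-0.80 ± 0.36 and -0.46 ± 0.15). Schwann cell genes were lower for 4 of 6 (5 adjusted over the list alone; SOX10 -3.09 ± 0.54) without a passing score (-0.41 ± 0.21). Duct and bile duct genes had 1 of 8 higher, SPP1 (1.67 ± 0.61), and 1 lower, KRT19 (-1.61 ± 0.61), 2 and 1 adjusted over the list alone. Their score was higher in 24 of 28 samples (0.62 ± 0.23).

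Beside these host markers, anterior HOX genes were lower in small intestinal liver metastases for 7 of 15 members (8 adjusted over the list alone; HOXB5 -4.79 ± 0.81, HOXD4 -3.36 ± 0.55) and posterior HOX genes for 7 of 15 (7 adjusted over the list alone; HOXB9 -9.71 ± 1.27). Both scores were lower in 19 of 28 samples (-0.58 ± 0.19 and -0.41 ± 0.14, adjusted permutation p = 0.0146 and 0.0289). Proliferation genes were lower for 13 of 27 (23 adjusted over the list alone), including UBE2C (-2.12 ± 0.58) and AURKB (-1.68 ± 0.49), while MKI67 (-1.14 ± 0.46) and the score (-0.32 ± 0.20) did not pass. Among primaries, replicate 39 had a proliferation score of 7.01 and replicate 8, the next highest, 4.56. Folds compare means, so replicate 39 may set part of these differences, and no fit without it was run. Islet hormone genes had 4 of 6 lower and 1 higher (4 and 1 adjusted over the list alone), with GCG at -5.90 ± 1.39 and SST at -10.44 ± 1.78, at medians under 1.3 CPM in primaries, and no passing score (-0.46 ± 0.22). Of the neuroendocrine secretory genes 3 of 22 were higher (3 adjusted over the list alone; PAM 1.36 ± 0.34, CPE 1.13 ± 0.37), and of the serotonin genes 2 of 14 (1 adjusted over the list alone; SLC18A2 3.15 ± 0.46), with scores that did not pass (0.07 ± 0.37 and -0.04 ± 0.29). SSTR2 (0.52 ± 0.38), PDX1 (0.54 ± 0.69) and MEN1 (0.05 ± 0.13) did not pass. The count was 2115 with limma-voom (1194 higher, 921 lower), 3386 with the Wilcoxon test (1834 higher, 1552 lower) and 1653 with host tissue scores as covariates, under which INS moved to 0.80 and MYH11 to 0.76. MYH11 then passed as higher (adjusted p = 0.0131 in edgeR), but it belongs to the smooth muscle list, whose score is among those covariates. KRT19 moved to 0.25 with limma-voom.

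**Figure D2:**
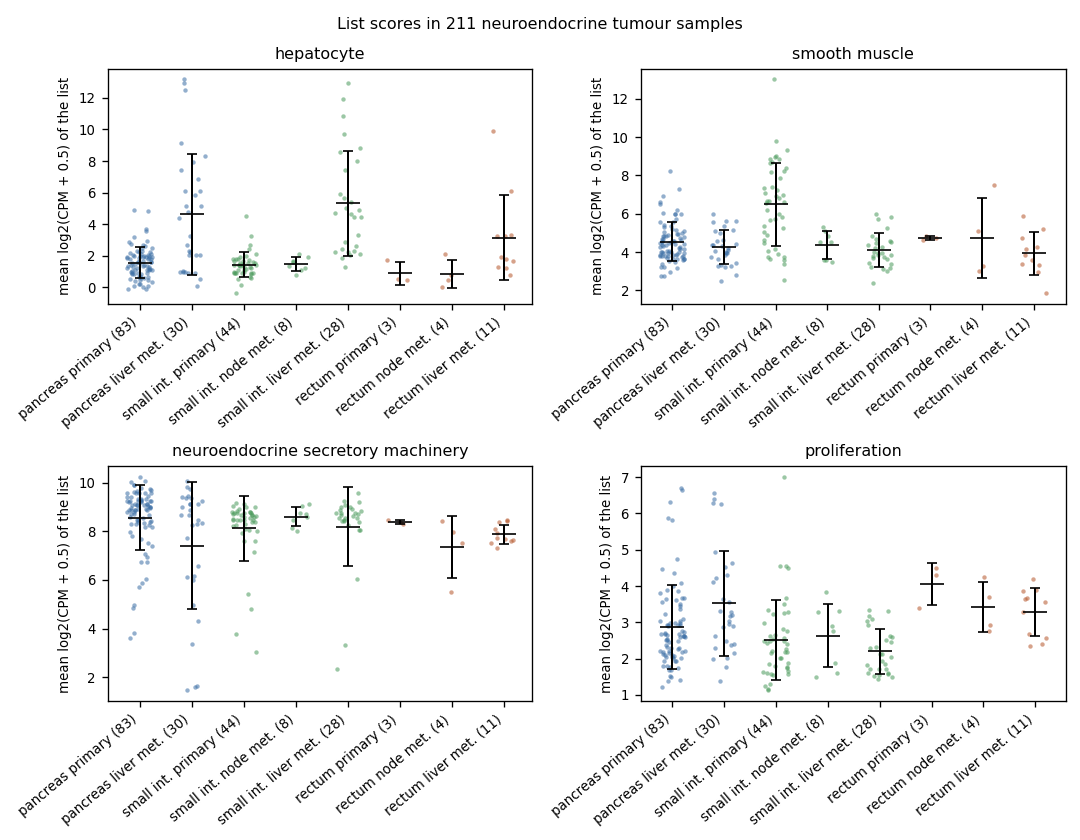
Scores of the hepatocyte, smooth muscle, neuroendocrine secretory and proliferation lists, as mean log2(CPM + 0.5) over members, in each sample of the 8 groups with the group mean and SD. Hepatocyte scores spread upward in liver metastases, and smooth muscle scores lie higher in small intestinal primaries than in liver metastases of that origin, by 2.40 log2 units in the means.

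The difference between both liver metastasis effects (small intestinal minus pancreatic) was tested directly. The difference was negative for the muscle genes ACTG2 (-7.39 ± 0.92), DES (-6.89 ± 1.06) and FLNC (-5.71 ± 0.68; 0.03 ± 0.41 in the pancreas) and the endothelin gene EDN3 (-5.35 ± 1.23). Proliferation genes moved apart, MKI67 by -2.82 ± 0.60 (adjusted p = 1.8e-04 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), as did 25 of 27 members (27 adjusted over the list alone). Small intestinal primary replicate 39, with a proliferation score of 7.01 against 4.56 in the next highest, weighs on these folds. GCG differed by 7.15 ± 1.53, the ghrelin acyltransferase MBOAT4 by 7.35 ± 0.90 and GHRLOS by 7.86 ± 0.94. Median GCG in primaries was 0.292 CPM in the small intestine and 14.0 in the pancreas, which left less room for a fall in the small intestine. APOA2 differed by 4.47 ± 1.40, and by 7.12 ± 1.55 without the low neuroendocrine libraries. It stood at -0.32 with host tissue scores as covariates, but it belongs to the hepatocyte list, whose score is among them. With limma-voom MKI67 stood at -1.57 and no longer passed. Of 2289 genes that passed, 464 had the higher effect in the small intestine and 1825 in the pancreas, and limma-voom gave 77 and the host covariates 1274.

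By list score, the smooth muscle effect differed by -2.11 ± 0.44 (9 of 10 members lower, 10 adjusted over the list alone) and the goblet and Paneth effect by -1.65 ± 0.46 (8 of 8 lower, 8 adjusted over the list alone). Islet hormones differed by 2.14 ± 0.49 (2 of 6 higher and 1 lower, 2 and 2 adjusted over the list alone), with a median member fold of -0.63, opposite in sign to the score. Of small intestinal primaries, 43 of 44 already lay below the pancreatic primary median of this score. It had less room to fall in the small intestine, so organ and starting level cannot be told apart here. Islet transcription factors differed by 0.91 ± 0.31 (2 of 18 higher and 2 lower, 2 and 2 adjusted over the list alone; median member fold 0.71, mean -0.02). The proliferation effect differed by -0.97 ± 0.36 and the posterior HOX effect by -0.63 ± 0.23 (8 of 15 lower, 8 adjusted over the list alone; HOXB9 -12.04 ± 1.43). Adjusted permutation p-values of these 6 lists ran from 0.00145 to 0.0401, and no other list passed, the hepatocyte effect differing by 0.83 ± 0.69 (adjusted permutation p = 0.354). Scores were not tested without the low neuroendocrine libraries. There 10 of 22 hepatocyte genes had a passing positive difference and 0 a negative one (median member fold 2.09). For erythroid genes it was 4 of 4 and 0 (4.84). Across 20936 genes the effects of both origins had a Pearson correlation of 0.404 and a Spearman correlation of 0.270, and genes are not independent replicates. Without the hepatocyte list Pearson's value was 0.383. Both effects were positive and passing for 827 genes against 239.1 for independent lists, both negative for 346 against 156.6, and opposite for 271. With host tissue scores as covariates Pearson's value fell to 0.262 and Spearman's rose to 0.357.

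**Figure D3:**
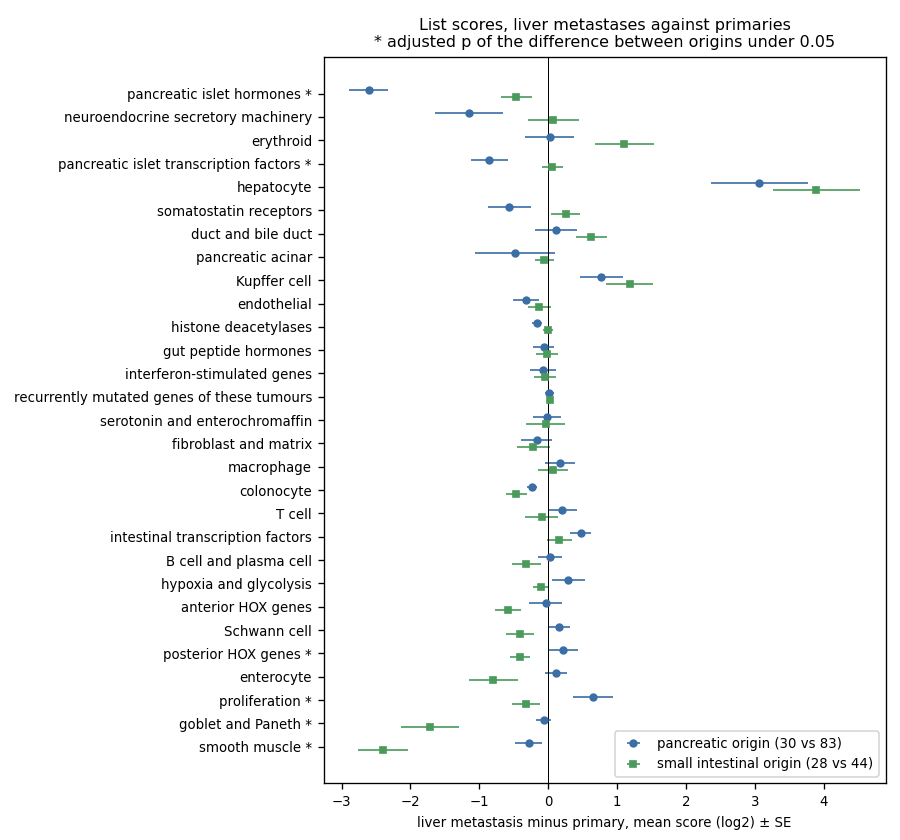
Liver metastasis minus primary difference of each of the 29 list scores (log2 units, ± SE) for pancreatic and small intestinal origin, with an asterisk where the difference between origins passed its permutation test. The smooth muscle list lies at -0.28 for the pancreas and -2.40 for the small intestine.

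Small intestinal lymph node metastases (n = 8) were compared with primaries (n = 44) and liver metastases (n = 28). Against primaries, the follicular complement receptor gene CR2 was higher by 4.63 ± 0.99 (13.7 CPM in node metastases), the lymphatic chemokine CCL21 by 3.15 ± 0.72 (90.6 against 11.4 CPM), and GSG1 and IGFN1 by 3.16 ± 0.74 and 2.94 ± 0.84. ACTG2 (-7.16 ± 1.53), GREM1 (-6.02 ± 1.44) and DES (-6.90 ± 1.76) were lower, as was PDX1 (-7.70 ± 1.98, 0.0206 against 0.210 CPM in the medians, with a primary mean of 10.4 and SD of 31.9). In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 331 genes passed, 58 higher and 273 lower, 317 of them at least 2-fold. In fits of these groups alone the real grouping gave 24 genes and other splits of the samples a median of 182. With 47 of 60 splits as large, chance could not be excluded. CHGA, TPH1, CDX2, SSTR2 and MKI67 did not pass, with medians of 49250, 471, 80.8, 16.8 and 14.3 CPM in the node metastases.

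B cell and plasma cell genes were higher in node metastases for 3 of 12 members (5 adjusted over the list alone; FCRLA 3.41 ± 0.81). That score was higher in 6 of 8 samples (1.54 ± 0.60, adjusted two-sided permutation p = 0.00898). Smooth muscle genes were lower for 7 of 10 (10 adjusted over the list alone; SYNM -4.75 ± 0.92), anterior HOX genes for 1 of 15 (4 adjusted over the list alone; HOXB5 -6.20 ± 1.59) and duct genes for 0 of 8 (3 adjusted over the list alone; KRT7 at -5.96 ± 1.95 did not pass). These scores differed by -2.14 ± 0.42 in 8 of 8 samples, -0.82 ± 0.19 in 8 of 8 and -0.94 ± 0.22 in 7 of 8 (adjusted permutation p = 0.0384, 0.0188 and 0.0487). Goblet and Paneth genes were lower for 7 of 8 (8 adjusted over the list alone; MUC2 -9.17 ± 2.03) and enterocyte genes for 3 of 10 (9 adjusted over the list alone), without passing scores. The count of changed genes was 24 in a fit of these groups alone (22 higher, 2 lower), 19 without the lowest 10% of libraries by depth (11 higher, 8 lower), 0 with the Wilcoxon test (2750 genes at an unadjusted p under 0.05, against 3170 with edgeR), 111 with limma-voom, 1223 with DESeq2 and 767 with host tissue scores, where DES stood at 1.01 and did not pass. DES belongs to the smooth muscle list, whose score is among those covariates, so that value does not test it. Leaving out the lowest 10% by depth removed node replicates 1, 2 and 3 (18.7, 19.4 and 13.9M), so its 19 genes rest on fewer node samples.

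Against node metastases, small intestinal liver metastases had higher FGG (13.02 ± 3.10), HRG (12.77 ± 2.70), HP (12.64 ± 3.11) and ALB (12.42 ± 2.63, 453 against 2.82 CPM) and lower PPEF2 (-6.77 ± 1.20), NKX2-3 (-5.86 ± 0.80), UNC45B (-5.69 ± 1.09) and IGFN1 (-4.25 ± 0.94). The hepatocyte list rose for 19 of 22 members (20 adjusted over the list alone). This list scored higher in 27 of 28 samples (3.84 ± 0.64). Duct genes rose for 2 of 8 (4 adjusted over the list alone; KRT7 7.36 ± 2.10). The score was higher in 28 of 28 samples (1.56 ± 0.23), and B cell genes fell for 5 of 12 (9 adjusted over the list alone; CR2 -4.10 ± 1.14). Their score was lower in 26 of 28 (-1.86 ± 0.60). Adjusted permutation p-values of these lists were 0.0175, 5.22e-04 and 0.00522. Islet transcription factors were higher for 5 of 18 (7 adjusted over the list alone; PDX1 8.24 ± 2.03, 0.143 against 0.0206 CPM in the medians), without a passing score (0.24 ± 0.15). In edgeR 1193 genes passed, 882 higher and 311 lower, 955 at least 2-fold. DESeq2 gave 2298, limma-voom 2675, the Wilcoxon test 2161 and the fit without the lowest 10% by depth 238. That last fit lacked node replicates 1, 2 and 3.

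Rectal liver metastases (n = 11) were compared with those of pancreatic origin (n = 30) to ask what differs with origin at a shared site. The gut peptide gene INSL5, made by enteroendocrine cells of the distal gut, was higher by 12.36 ± 0.83 (1160 against 0.0578 CPM), with PRAC1 (11.19 ± 1.36), the disaccharidase gene SI (9.22 ± 1.18), the cytochrome gene CYP2W1 (8.22 ± 0.77, 1515 against 0.879 CPM) and PSCA (8.10 ± 0.82). The endothelin gene EDN3 (-11.59 ± 2.12), the islet factor IRX2 (-10.61 ± 1.97) and SPINK1 (-10.18 ± 2.03) were lower. CHGA was lower too (-3.29 ± 1.01, 31.6 against 1755 CPM), while SYP (-0.22 ± 0.41) did not pass. Other higher genes were IZUMO2 (9.57 ± 0.81), TNNC1 (8.44 ± 0.82) and GHRL (8.36 ± 1.10), and other lower ones HAP1 (-9.21 ± 2.08), TMEM179 (-7.88 ± 0.95), SLC8A2 (-7.76 ± 0.90), GRIK3 (-7.60 ± 1.20) and CHD5 (-7.44 ± 1.04). In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 8261 genes passed, 3135 higher and 5126 lower, and 5530 differed at least 2-fold.

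Of the anterior HOX genes 13 of 15 were lower in rectal than in pancreatic liver metastases (14 adjusted over the list alone; HOXC5 -7.54 ± 1.45). That score was lower in 11 of 11 samples (-1.12 ± 0.24, adjusted two-sided permutation p = 0.02). Posterior HOX genes were lower for 14 of 15 and higher for 1 (14 and 1 adjusted over the list alone; HOXC10 -9.90 ± 2.03), yet 11 of 11 rectal samples had a score above the pancreatic median and the score did not pass (-0.11 ± 0.20). Islet transcription factors had 10 of 18 lower and 3 higher (10 and 3 adjusted over the list alone; NKX6-1 -11.81 ± 1.93), a median member fold of -2.44 and a score of 0.07 ± 0.25 that did not pass. Enterocyte genes had 4 of 10 higher and 3 lower (4 and 4 adjusted over the list alone), with SI higher and ALPI lower (-8.26 ± 2.02), a median fold of -0.25, a mean of 0.06. Their score was higher in 11 of 11 samples (1.77 ± 0.19). Colonocyte genes had 3 of 8 higher and 1 lower (3 and 1 adjusted over the list alone; CA1 2.44 ± 0.55), with a median fold of -0.06, a mean of 0.19. That score was higher in 11 of 11 (0.38 ± 0.11, adjusted permutation p = 0.00573). Schwann cell genes had 2 of 6 higher and 1 lower (2 and 1 adjusted over the list alone; CDH19 4.74 ± 0.74), with a median of -0.19, a mean of 0.19. This list scored higher in 11 of 11 (1.22 ± 0.19). Fibroblast and matrix genes were lower for 13 of 19 and higher for 1 (14 and 1 adjusted over the list alone; COL5A2 -2.13 ± 0.49; score -1.23 ± 0.41, 10 of 11 samples). Histone deacetylases had 3 of 11 higher and 1 lower (3 and 1 adjusted over the list alone; HDAC10 1.60 ± 0.24; score 0.35 ± 0.09, 10 of 11 samples).

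Serotonin genes were lower in rectal than in pancreatic liver metastases for 6 of 14 members and higher for 1 (6 and 1 adjusted over the list alone), TPH1 by -6.19 ± 1.57 (0.345 against 4.06 CPM), without a passing score (-0.25 ± 0.21). Proliferation genes were lower for 6 of 27 (6 adjusted over the list alone; MKI67 -2.03 ± 0.72, 15.4 against 16.7 CPM in the medians), without a passing score (-0.24 ± 0.33). Acinar genes were lower for 16 of 18 and higher for 1 (16 and 1 adjusted over the list alone; PRSS1 -13.89 ± 3.02, 0.0327 against 0.277 CPM, with a pancreatic mean of 1015 and SD of 5380), yet 11 of 11 rectal samples lay above the pancreatic median score, and the score did not pass (-0.72 ± 0.52). GCG was higher (6.45 ± 1.33, 1.32 against 0.0588 CPM) and CDX2 lower (-4.57 ± 1.12), MEN1 was higher by 0.53 ± 0.19, and SSTR2 (-0.13 ± 0.57) and ALB (-3.20 ± 1.44) did not pass. With limma-voom SSTR2 stood at 1.61 and passed. Depth and origin cannot be told apart here, since 17 of 18 rectal libraries held over 90M counts and no pancreatic library did, and with that division as a covariate 398 genes passed. Among named genes of all contrasts, 34 calls no longer passed with it. With log2 library size as a covariate 7836 genes passed, of which 5360 were shared with the full comparison. The Wilcoxon test gave 3331 higher and 2703 lower.

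Against small intestinal liver metastases (n = 28), rectal liver metastases again had higher INSL5 (11.63 ± 0.84), with GPR12 (11.15 ± 1.27), PSCA (10.18 ± 0.91), CYP2W1 (9.85 ± 0.84), the caudal homeobox gene HOXB13 (9.77 ± 1.22, 366 against 0.0295 CPM) and the peptide YY receptor NPY2R (9.67 ± 1.71). The dopamine receptor gene DRD5 (-11.74 ± 2.10), the ghrelin receptor GHSR (-11.06 ± 1.98) and HOXC6 (-10.85 ± 1.65) were lower. CHGA fell by 5.40 ± 1.15 (31.6 against 26920 CPM), TPH1 by 9.67 ± 1.85 (0.345 against 1492 CPM) and CDX2 by 7.61 ± 1.32 (0.164 against 59.6 CPM). The near-identical MBD3L2 (-12.06 ± 2.27), MBD3L3, MBD3L4 and MBD3L5 were lower, with uncertain separate values. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 7056 genes passed, 3636 higher and 3420 lower, and 4515 differed at least 2-fold.

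Serotonin and enterochromaffin genes were lower in rectal than in small intestinal liver metastases for 8 of 14 members and higher for 1 (8 and 1 adjusted over the list alone), with TAC1 at -8.97 ± 1.94 and SLC18A1 at -4.91 ± 1.46. This list scored lower in 11 of 11 samples (-2.14 ± 0.25, adjusted two-sided permutation p = 1.24e-04). Islet hormone genes were higher for 3 of 6 (3 higher and 1 lower adjusted over the list alone; GCG 7.33 ± 1.56, SST 6.03 ± 1.60; score 1.40 ± 0.42, 10 of 11 samples). Islet transcription factors had 4 of 18 higher and 5 lower (5 and 5 adjusted over the list alone), MAFA at 10.84 ± 1.44 and NKX6-1 at -8.17 ± 1.68, with a median fold of -0.57, a mean of -0.82. The score was higher in 11 of 11 samples (0.93 ± 0.12). Proliferation genes were higher for 11 of 27 (13 adjusted over the list alone; CDC20 2.26 ± 0.63, AURKB 1.92 ± 0.63). Their score was higher in 11 of 11 samples (1.09 ± 0.23, adjusted permutation p = 4.35e-04), while MKI67 (0.64 ± 0.63) did not pass. Anterior HOX genes were lower for 8 of 15 and higher for 1 (9 and 1 adjusted over the list alone; HOXC5 -10.81 ± 1.66; score -1.54 ± 0.19, 11 of 11 samples). Intestinal transcription factors had 2 of 11 higher and 3 lower (2 and 4 adjusted over the list alone; ISX 6.46 ± 0.95; score -0.45 ± 0.12, lower in 11 of 11).

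Enterocyte genes had 2 of 10 higher and 3 lower in this comparison (3 and 3 adjusted over the list alone), with SI at 9.74 ± 1.25 and ALPI at -4.67 ± 1.66, and Schwann cell genes 2 of 6 higher (3 adjusted over the list alone; GFRA3 5.50 ± 1.22). Both scores were higher in 11 of 11 rectal samples (1.64 ± 0.18 and 1.50 ± 0.16). Interferon-stimulated genes were lower for 5 of 17 (5 adjusted over the list alone; MX2 -3.19 ± 0.52), without a passing score (-0.57 ± 0.20, adjusted permutation p = 0.0642). SYP, SSTR2 (0.73 ± 0.55) and ATRX (-0.47 ± 0.23) did not pass, and the acinar gene CPB1 was higher (10.49 ± 1.49, 10.1 CPM in rectal metastases). With total counts over 90M as a covariate 868 genes passed, and in libraries above that depth alone, which leaves 2 small intestinal samples, 1095 passed, of which 1012 were shared with the full comparison. With log2 library size as a covariate 7440 passed (3251 higher, 4189 lower), 4927 of them shared, and DESeq2 gave 3254 higher and 4548 lower.

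Within the rectum, liver metastases (n = 11) were compared with 3 primaries and 4 node metastases, groups too small for fine estimates. The peptide hormone genes PYY (-9.83 ± 1.41, 2.25 against 103 CPM) and PPY (-11.26 ± 2.83, 0.341 against 94.2 CPM) were lower in liver metastases than in primaries, as were MARCHF11 (-8.10 ± 1.38) and PAX4, an islet and enteroendocrine factor (-7.27 ± 1.93). LRP3 (3.08 ± 0.68), the histone gene H2AJ (2.59 ± 0.69) and the related pseudogenes POM121L8P (3.08 ± 0.69) and BCRP2 (3.07 ± 0.72), whose separate values are uncertain, were higher. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 114 genes passed, 11 higher and 103 lower, 113 at least 2-fold. In fits of these groups alone 10 of 100 splits of the samples gave as many genes, so chance could not be excluded. CHGA (4.17 ± 2.03), MKI67, SSTR2 and ALB did not pass. Gut peptide hormones had 1 of 12 higher and 1 lower (1 and 1 adjusted over the list alone), a median fold of -0.10, a mean of 0.18. This list scored lower in 11 of 11 samples (-1.20 ± 0.30, adjusted exact permutation p = 0.0283). Posterior HOX genes had 1 of 15 lower (5 adjusted over the list alone; HOXA11 -6.63 ± 1.77). The score was lower in 11 of 11 (-0.39 ± 0.18, adjusted exact permutation p = 0.0384), where the smallest unadjusted p for 11 against 3 is 0.0027. With 1 primary left out that p is at least 0.013, too large to pass here, so neither score could be tested in this way. The count was 40 without primary replicate 2 and 188 without replicate 3, 545 with limma-voom (202 higher, 343 lower), 306 with DESeq2 (230 higher, 76 lower, so mostly in the other direction), 209 without a filter, 179 with host tissue scores, 50 in a fit of these groups alone, and 0 with the Wilcoxon test (1619 genes at an unadjusted p under 0.05, 1562 with edgeR).

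Against rectal node metastases, liver metastases had lower SFRP2 (-12.56 ± 1.93), the microfibril gene MFAP5 (-7.91 ± 1.59, 0.0545 against 9.98 CPM) and the identical-valued copies HNRNPCL1 and HNRNPCL3 (-7.95 ± 2.17). LAMC3 (5.75 ± 1.54, 14.7 against 0.164 CPM), SEMA3G (3.36 ± 0.97) and TATDN2 (2.79 ± 0.73) were higher, as was DSCR8, with a median of 19.6 CPM against 0 in node metastases, too near the floor for a fold. T cell genes were lower for 2 of 12 members (12 adjusted over the list alone; IL7R -3.33 ± 0.98). Their score was lower in 11 of 11 samples (-1.60 ± 0.74, adjusted exact permutation p = 0.0106), and B cell genes for 6 of 12 (11 adjusted over the list alone; MS4A1 -6.69 ± 1.55), without a passing score (-1.37 ± 1.46). Posterior HOX genes were lower for 4 of 15 (9 adjusted over the list alone; HOXA11 -8.12 ± 1.83), anterior HOX genes for 1 of 15 (5 adjusted over the list alone; HOXC5 -5.50 ± 1.48) and Schwann cell genes for 1 of 6 (2 adjusted over the list alone; SOX10 at -2.70 ± 1.03 did not pass). Those scores differed by -0.50 ± 0.25 (11 of 11 lower), -1.01 ± 0.42 (10 of 11) and -1.0 ± 0.39 (11 of 11), with adjusted exact permutation p of 0.0143, 0.017 and 0.0289. The 4 passing scores also passed without node replicate 1 or 2, all but the Schwann cell score without replicate 3, and only that of posterior HOX genes with 1 sample per patient. In edgeR 499 genes passed, 63 higher and 436 lower, 490 at least 2-fold. The count was 97 with 1 sample per patient, 238 without node replicate 3, 796 with DESeq2, 750 with limma-voom, 285 and 194 under the 2 corrections for depth over 90M, 233 in a fit of these groups alone, 197 with host tissue scores, and 0 with the Wilcoxon test (1953 genes at an unadjusted p under 0.05, 2959 with edgeR).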

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

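The chance splits and the library size tests were chosen only after the results were seen, and the other tests and their bounds were written before. Genes higher in liver metastases could come from hepatocyte RNA in the samples, from a difference in library size, or from the tumour cells. Across small intestinal liver metastases, 1008 genes that rose at least 2-fold, outside the list, had a median correlation of 0.648 (0.329 to 0.791, n = 28) with the hepatocyte score, which fits hepatocyte RNA, and across pancreatic ones 1618 such genes had 0.479 (0.146 to 0.662, n = 30), which leaves it open. With log2 library size as covariate 96.2% of 1640 and 94.4% of 1030 genes that rose at least 2-fold in the pancreas and small intestine were still called. Median depths of primaries and liver metastases were alike (28.8M and 30.4M pancreatic, 28.7M and 30.7M small intestinal). This covariate could therefore hardly remove the calls, and no conclusion is drawn from it. Pearson correlations of the neuroendocrine and hepatocyte scores were negative, while Spearman's values did not pass. In pancreatic liver metastases r was -0.410 (-0.720 to 0.333, permutation p = 0.0223, adjusted 0.0390), with a Spearman value of -0.028 (permutation p = 0.883). In small intestinal ones r was -0.643 (-0.816 to -0.055, permutation p = 0.00052, adjusted 0.00182), with a Spearman value of -0.20 (permutation p = 0.309). Both Pearson values rest on few samples, since without the 2 farthest r was -0.070 and -0.436. Changes of the tumour cells themselves were not tested and stay open.

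Lower genes in pancreatic liver metastases could come from normal pancreas in the primaries or from the tumour cells. Across 83 pancreatic primaries, 532 genes that fell at least 2-fold, outside the acinar list, had a median correlation of -0.024 (-0.061 to 0.007) with the acinar score, so acinar RNA is excluded as their common source. The islet hormone score rose with the acinar score in these primaries at r = 0.275 (0.054 to 0.463, permutation p = 0.0116, adjusted 0.0270; Spearman 0.359, p = 0.001, adjusted 0.007), and at 0.229 without the 2 farthest samples. For the islet hormone genes normal pancreas and tumour cells cannot be told apart by this test.

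Differences between rectal and small intestinal liver metastases could come from library kind or depth, or from origin. Among 7056 called genes the 2 deep small intestinal libraries lay in the rectal direction for 45.8% (34.95 to 60.95), against a median of 48.5% and a highest value of 69.5% in 200 random pairs of libraries. With 2 libraries this leaves library kind open, and depth over 90M need not mark 1 kind of library.

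Splits of the same samples asked whether chance assignment could give as many changed genes, in fits on those samples alone. The real grouping is counted among the splits. Excluded means that no other split gave as many genes, among the limited number run. Chance assignment was excluded for primaries of both organs (8627 genes, highest other 559, median of other splits 329, 1 of 35 splits as large). It was excluded as well for pancreatic liver metastases (3635, highest other 1698, median 308, 1 of 40) and small intestinal ones (3422, highest other 1489, median 298, 1 of 60). The difference of both effects gave 1709 (highest other 1086, median 489, 1 of 22). Its splits shuffled site within each organ, which also removes any effect common to both, so they cannot exclude chance for the difference. Chance was also excluded for rectal against pancreatic (6108, highest other 2069, 1 of 80) and small intestinal liver metastases (7669, highest other 1733, 1 of 80). Small intestinal liver against node metastases gave 1667 (highest other 2602, 2 of 100). Another split gave more genes there, so chance was unlikely but not excluded. Rectal liver against node metastases gave 233 genes (highest other 1658, 4 of 100) with both samples of 1 patient kept. With 1 sample per patient they gave 18 (highest other 473, 20 of 100), and chance could then not be excluded. That setting drops 1 of the 4 node samples, so the repeated patient cannot be told apart from the values of the dropped sample. Nor could it be excluded for small intestinal node metastases against primaries (24, highest other 1457, 47 of 60) and for rectal liver metastases against primaries (50, highest other 239, 10 of 100).

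Dixon's test, applied to 89 values in the small groups, marks about 1 in 20 groups by chance, and marked 9. In small intestinal node metastases 1 sample stood apart for each of CHGA (ratio 0.650), INS (0.935), GCG (0.557) and PRSS1 (0.730). Islet hormone scores of this group ran from -0.979 to -0.082, near the lowest value possible, so the INS and GCG ratios may only reflect values at the floor. In rectal node metastases 1 sample stood apart for each of the intestinal transcription factor (0.844), T cell (0.840) and B cell (0.878) scores and for SSTR2 (0.839) and PRSS1 (0.850). Whether the same sample was behind several of these marks was not examined. No sample was left out for this.

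The liver metastasis effect differed between small intestine and pancreas for the scores of islet hormones (2.14), islet transcription factors (0.91), posterior HOX genes (-0.63), proliferation (-0.97), goblet and Paneth cells (-1.65) and smooth muscle (-2.11). It differed for GHRLOS (7.86), MBOAT4 (7.35), GCG (7.15), APOA2 (4.47), MKI67 (-2.82), EDN3 (-5.35), FLNC (-5.71), DES (-6.89), ACTG2 (-7.39) and HOXB9 (-12.04). Organ of origin is the difference the design names here. For the islet lists and GCG, small intestinal primaries started lower than pancreatic ones and had less room to fall. The starting level cannot be told apart from a difference of effects there. Of 2289 genes with such a difference in the report, the count became 2231 with library size as covariate, 2200 with depth over 90M as covariate and 1274 with host tissue scores. Under the latter APOA2, itself part of the hepatocyte score, stood at -0.32.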

How the results depend on the processing

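Fits with the depth limit of 90M, without low neuroendocrine libraries and without the smallest library were chosen only after the results were seen. Of the gene counts, 119 alternatives stayed within 1.5-fold of the value in the report and 39 did not, and the cause was not tested. The larger direction also turned in some, as for rectal liver metastases against primaries with DESeq2 (230 higher, 76 lower). For small intestinal against pancreatic primaries (9620 genes) the alternatives gave 7948 to 10700. Pancreatic liver metastases against primaries (4568) gave 1804 with limma-voom, 1240 with the Wilcoxon test, 2817 with host tissue scores and 2103 without low neuroendocrine libraries, and small intestinal ones (3901) gave 2115 with limma-voom and 1653 with host tissue scores. Small intestinal node metastases against primaries (331) gave 1223 with DESeq2, 111 with limma-voom, 24 in the groups alone, 19 without the lowest 10% by depth, 767 with host tissue scores and 0 with the Wilcoxon test, where 2750 genes had an unadjusted p under 0.05. Small intestinal liver against node metastases (1193) gave 2298 with DESeq2, 2675 with limma-voom, 2161 with the Wilcoxon test and 238 without the lowest 10% by depth. Leaving out the lowest 10% removed small intestinal node replicates 1, 2 and 3, so the 19 and 238 genes rest on fewer node samples. With total counts over 90M as a covariate, rectal against pancreatic liver metastases (8261) gave 398 and rectal against small intestinal ones (7056) gave 868, or 1095 in deep libraries alone, while log2 library size as a covariate gave 7836 and 7440.

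Rectal liver metastases against primaries (114) gave 209 without a filter, 306 with DESeq2, 545 with limma-voom, 50 in the groups alone, 179 with host tissue scores and 0 with the Wilcoxon test, where 1619 genes had an unadjusted p under 0.05. Leaving out 1 primary gave 40 (replicate 2) to 188 (replicate 3). Against node metastases (499) the values were 796 with DESeq2, 750 with limma-voom, 233 in the groups alone, 197 with host tissue scores, 97 with 1 sample per patient, 285 with the depth covariate, 194 in deep libraries alone and 0 with the Wilcoxon test, where 1953 genes had an unadjusted p under 0.05. Leaving out 1 node metastasis gave 97, in the same fit as with 1 sample per patient, to 561 (replicate 2), and 238 without replicate 3. The difference of liver metastasis effects (2289) gave 77 with limma-voom and 1274 with host tissue scores, and their correlation (0.404) was 0.540 in the groups alone and 0.262 with host tissue scores, where Spearman's value rose from 0.270 to 0.357. List scores passing (59) ranged from 52 to 61. Of the 4 list calls against rectal node metastases, 4 held without replicate 1 or 2, 3 without replicate 3 and 1 with 1 sample per patient, while too few primaries remain to test theirs with 1 left out.

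Among the values of named genes, 4647 stayed alike, 356 no longer passed, 42 passed only in the alternative and 20 turned in direction. Values that passed in neither fit count as alike whatever their sign. The 20 therefore cover only genes that passed in the report, in the alternative or in both. Of those no longer passing, 34 came with total counts over 90M as a covariate and 14 in deep libraries alone. With host tissue scores PRSS1 stood at 0.0714 in small intestinal against pancreatic primaries (adjusted p = 0.921 in edgeR), INS at 0.80 and MYH11 at 0.76 in small intestinal liver metastases, DES at 1.01 in small intestinal node metastases and APOA2 at -0.32 in the difference of effects. The same covariates gave CELA3B -0.23, MAFA 0.0135 and ONECUT1 -1.08 in pancreatic liver metastases. PRSS1, MYH11, DES, APOA2 and CELA3B belong to lists whose scores are these covariates, so these values do not test their differences. CELA3B also stood at -4.19 with DESeq2, where it passed as lower, and without passing at -1.56 with limma-voom and -1.68 with the Wilcoxon test. Between primaries HHEX stood at -1.12 with DESeq2 and -0.48 with the Wilcoxon test and passed as lower in both. CA9 stood at 0.0622 and 0.15 and CR2 at 0.66 and 0.72 with limma-voom and the Wilcoxon test. KRT19 stood at 0.25 and 0.30 with those tests in small intestinal liver metastases, and SSTR2 at 1.61 with limma-voom in rectal against pancreatic liver metastases (adjusted p = 0.0339). No paired analysis was possible because the samples are separate patients' tumours, apart from 1 patient who contributed 2.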

Other observations

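The genes below were chosen only after their values were seen, while the proliferation test was written before. In liver metastases of both origins, outside all lists, 21 genes were higher and 33 lower in the designed fit, with host tissue scores as covariates, and without low neuroendocrine libraries. The mechanically gated channel gene PIEZO2 was higher by 1.25 ± 0.25 in pancreatic and 1.21 ± 0.30 in small intestinal liver metastases, the deubiquitinase OTULIN by 0.62 ± 0.11 and 0.67 ± 0.13, and GPLD1, a gene expressed in liver, by 1.68 ± 0.28 and 1.82 ± 0.34. Also higher was HRG, a plasma protein gene of the liver (11.25 ± 0.83 and 10.43 ± 1.07). Lower were SFRP2 (-5.19 ± 0.81 and -6.06 ± 0.90) and NKX2-3 (-2.89 ± 0.55 and -6.85 ± 0.73). Host tissue not captured by the covariates could hold such genes, since the median correlation of genes at least 2-fold higher with the hepatocyte score was 0.479 in pancreatic and 0.648 in small intestinal liver metastases. Staining of SFRP2 and PIEZO2 in sections would show which cells carry them.

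If proliferation rises as the neuroendocrine programme is lost, both scores should move against each other in every group. In pancreatic primaries they did, at r = -0.516 (-0.684 to -0.252, permutation p = 3e-05, adjusted 0.00021), but Spearman's value was -0.189 (p = 0.0872, adjusted 0.203) and r was -0.357 without the 2 farthest samples. Small intestinal primaries had r = -0.319 (-0.622 to 0.036, p = 0.0414, adjusted 0.0579; Spearman -0.319, p = 0.0343, adjusted 0.12), and -0.159 without the 2 farthest. Pancreatic liver metastases had r = -0.052 (-0.504 to 0.303, p = 0.788; Spearman -0.102, p = 0.590) and small intestinal ones r = 0.065 (-0.260 to 0.328, p = 0.763; Spearman -0.106, p = 0.589), with -0.274 and -0.083 without the 2 farthest. In pancreatic replicates 1, 25 and 27 hepatocyte scores were 12.9, 13.2 and 12.5. Their neuroendocrine scores were 1.46, 1.62 and 1.58 and their proliferation scores 2.28, 1.77 and 2.03. Liver RNA in a sample can lower both scores together, so r cannot decide the matter in liver metastases. The idea is left open by these values, and counts of dividing cells in stained sections of the same tumours would test it.

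MKI67 was higher in pancreatic liver metastases (1.68 ± 0.36), stood at -1.14 ± 0.46 in small intestinal ones without passing, and differed between the organs by -2.82 ± 0.60. Small intestinal medians were close (6.90 against 7.56 CPM), and high samples set that mean (22.0 CPM with an SD of 57.5 in primaries). The highest was primary replicate 39, at 8.53 in log2(CPM + 0.5). Limma-voom gave -0.05 in the small intestine and -1.57 for the difference, which did not pass. A difference in grade between the sampled groups could give this, and so could low neuroendocrine libraries, but without the latter the difference was -2.79 ± 0.62. Grade was not tested, and grade given for each sample would separate these readings.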
